A study of Mus musculus with 10 samples.

How the data were processed

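RNA of 10 mouse melanoma tumours was measured on Affymetrix whole-transcript arrays, 1 per tumour, with 5 exercise and 5 non-exercise arrays grouped by the titles. Per the labels' protocols, RNA was isolated with the RNeasy mini or the RNeasy Lipid tissue mini kit without saying which tumour had which, amplified to cRNA, made into single-stranded cDNA and end-labelled with biotin. Per the submitters' processing notes the values were summarised with PLIER, whose version is not given in the sources used here. The table holds values the authors deposited per probe set, taken as log2 because they lie between 4.66 and 14.55; the log base, any added constant and the step between arrays are not given in the sources used here. No scan date or slide was used here, so neither was tested as a batch.

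The design fixed before the data were examined called for quantile normalization if array medians differed by over 0.1. They differed by 0.126, and the deposited table was quantile normalized with limma 3.58.1 in R 4.3.3; the table as deposited is an alternative. Of 35556 probe sets, 21789 had 1 gene symbol in the platform table, 1621 had several and 12146 were not listed. Those with 1 gene were named through Entrez identifiers in the mouse annotation GRCm38.p6, used only for names; 21698 matched and 0 symbols changed. For the 999 genes with several probe sets the one with the highest mean was used. No filter on dim probe sets was applied, and a genome build for coordinates is not given in the sources used here, so none are printed.

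Genes were compared with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over 19938 genes at 0.05. Gene lists, 35 fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation, with fry and by exact permutation of the list score. Of the listed genes 76 were not analysed here. Scores were compared over all 252 assignments of 10 arrays. Correlations used 100000 resamples, or all 5040 orders where only 7 arrays were used. Centred correlations were resampled across both groups, whose spread differed, so their permutation p are approximate. With a covariate, group labels moved while the covariate stayed with its array, so those permutation p are approximate too. The named genes are the 10 largest increases and decreases past the threshold, up to 4 members with the smallest p in each called list and in 6 fixed lists, and 19 fixed genes, of which 16 were measured; predicted genes, clones and olfactory receptors were passed over. Alb, Ttr, Xist, Kdm5d, Eif2s3y, Uty and members of 4 added lists (hepatocytes, cholesterol synthesis, mitochondrial ribosome, mRNA splicing factors) were chosen after seeing the data. Arrays were compared in pairs before averaging, and the most values shared exactly by a pair was 1.

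Other settings tried were the deposited table, median centring, filters on dim genes, the mean of probe sets, eBayes without the trend or with robust variances, array weights, an ordinary test per gene, an exact Wilcoxon test, adjusted p thresholds of 0.10 and 0.25, covariates for melanocytic, muscle and keratinocyte scores, and leaving out each array in turn. Pseudocounts on a linear scale were not run because the table is on a log scale. Leaving out 3 arrays and covariates for hepatocyte and adipocyte scores were added after seeing the data. The code was tested on 10 simulated data sets of 19938 genes for the exercise comparison, with 200 changed genes: 75.8% of changes of 0.5 and 97.9% of changes of 1 on the log2 scale were recovered, with 8.7 false calls on average, and a list shifted by 0.5 was called in 10 of 10. The simulated genes were independent of each other, while the estimated correlation within the real lists had a median of 0.264 and reached 0.911. The simulation thus checks the code and does not test the list calls on these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.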

Results

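Transcript levels were measured on whole-transcriptome arrays in 10 melanoma tumours of mice, 5 from exercised and 5 from non-exercised animals. The series title names voluntary exercise and the entry of natural killer (NK) cells into tumours, and the comparison of the groups asks which transcripts and immune cell markers differ with exercise. Each array held 35556 probe sets, of which 21789 were paired with 1 gene and gave 19938 genes. The deposited array medians lay between 8.64 and 8.77 on the scale of the table, taken to be log2 from its range. Pairs of arrays correlated across genes at 0.976 to 0.990 within the exercise group, 0.987 to 0.996 within the non-exercise group and 0.960 to 0.991 between groups, and no pair was a copy of another. The number of arrays limits the precision of the values. Each title carries its own number, but the labels do not say that a number is an animal, so p-values measure the spread between these tumours. All changes are exercise minus non-exercise, with the standard error (SE) after ±.

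Tnfrsf12a, the receptor of the cytokine TWEAK, was 3.02-fold higher, at 11.72 ± 0.19 in the exercise arrays and 10.13 ± 0.20 in the non-exercise arrays (SD, n = 5 each), a log2 change of 1.59 ± 0.10 (limma adjusted p = 4.58e-06). Il1rn, the interleukin-1 receptor antagonist, rose by 1.74 ± 0.21 (limma adjusted p = 0.000209), and Lilr4b, a gene of the leukocyte immunoglobulin-like receptor family, by 1.63 ± 0.20 (limma adjusted p = 0.000253). Clec2d, a C-type lectin bound by NK cell receptors of the Nkrp1 family, rose by 1.75 ± 0.25 (limma adjusted p = 0.000474). The interferon-induced genes Slfn4 and Ifi205 changed by 1.68 and 1.65, and all 5 exercise arrays lay above all non-exercise arrays for these 6 genes. Serpinb2, an inhibitor of plasminogen activators, changed by 1.95 with 4 exercise arrays above all others. The remaining 3 of the 10 largest increases were Cyp2e1 (2.06), Retn (1.73) and H2-Aa (1.54). Cyp2e1, an enzyme abundant in hepatocytes, no longer passed without exercise array 309 or 310 or non-exercise array 326 or 330, and Retn, the adipokine resistin, without exercise array 300, 309 or 310 or non-exercise array 326, 327, 330 or 331 (adjusted p 0.000299 to 0.0578 and 0.00440 to 0.117 leaving out 1 array; log2 changes from 1.70 and 1.31). Without the 3 exercise arrays (306, 309 and 310) that held hepatocyte transcripts, Cyp2e1 (0.51), Retn (1.11) and H2-Aa (0.39) did not pass.

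Zfp213, a zinc finger protein, was 2.14-fold lower, a log2 change of -1.10 ± 0.07 (limma adjusted p = 4.77e-06). Ddit4, an inhibitor of mTORC1 induced by stress, changed by -1.09 ± 0.08 (limma adjusted p = 6.09e-06), and Atg101, a subunit of the complex that starts autophagy, by -1.07 ± 0.08 (limma adjusted p = 8.59e-06). Chac1 (-0.96) and Sesn2 (-0.87), targets of the integrated stress response, were also among the 10 largest decreases, with Dglucy (-0.95), Ppp1r16b (-0.93), the matrix protein gene Npnt (-0.92), the complex III subunit Uqcrfs1 (-0.87) and the ATP-gated channel gene P2rx3 (-0.87). P2rx3 had 2 probe sets that disagreed, with log2 changes of -0.87 and -0.11, and its call was lost without exercise array 300, 309 or 310 or non-exercise array 326, 327 or 331 (adjusted p 0.00195 to 0.0723 leaving out 1 array). The log2 change of P2rx3 was -0.70 without the 3 arrays with hepatocyte transcripts, and did not pass.

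In all, 1266 genes were higher and 2118 lower at a limma adjusted p under 0.05, which is 17.0% of those tested. The change exceeded 2-fold for 125 of the higher and 3 of the lower genes, and the median log2 change of the called genes was 0.41 and -0.32. All exercise values lay above all non-exercise values for 746 genes and below for 1660, where chance gives 0.794% of genes for the directions together and 79.1 genes for each. Of the called genes 37.4% were higher, and 23.4% after centring the arrays on their medians. The genes higher in exercise then numbered 938, and the genes lower in exercise 3076.

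Transcripts of hepatocytes were high in 3 of the 5 exercise arrays, 306, 309 and 310. Alb, which encodes albumin, lay between 12.28 and 12.97 in these arrays and between 6.84 and 9.22 in the other 7. Ttr, which encodes the carrier transthyretin, lay between 9.01 and 10.40 against 7.07 to 7.44. For 24 of 26 measured hepatocyte genes, all 3 arrays lay above all other arrays. Of these 26 genes, 5 rose and none fell in the comparison of the groups, and 19 rose when adjusted over the list alone (exact permutation p = 0.143 for the score; adjusted p = 0.231 with an estimated correlation). The hepatocyte score, the mean centred log2 level of the list, was between 0.89 and 1.5 in these arrays and between -0.63 and -0.36 in the others. The list was written after the values were seen. Without these 3 arrays, an alternative also chosen after seeing the data, the genes higher in exercise numbered 746 and the genes lower in exercise 1607.

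**Figure D1:**
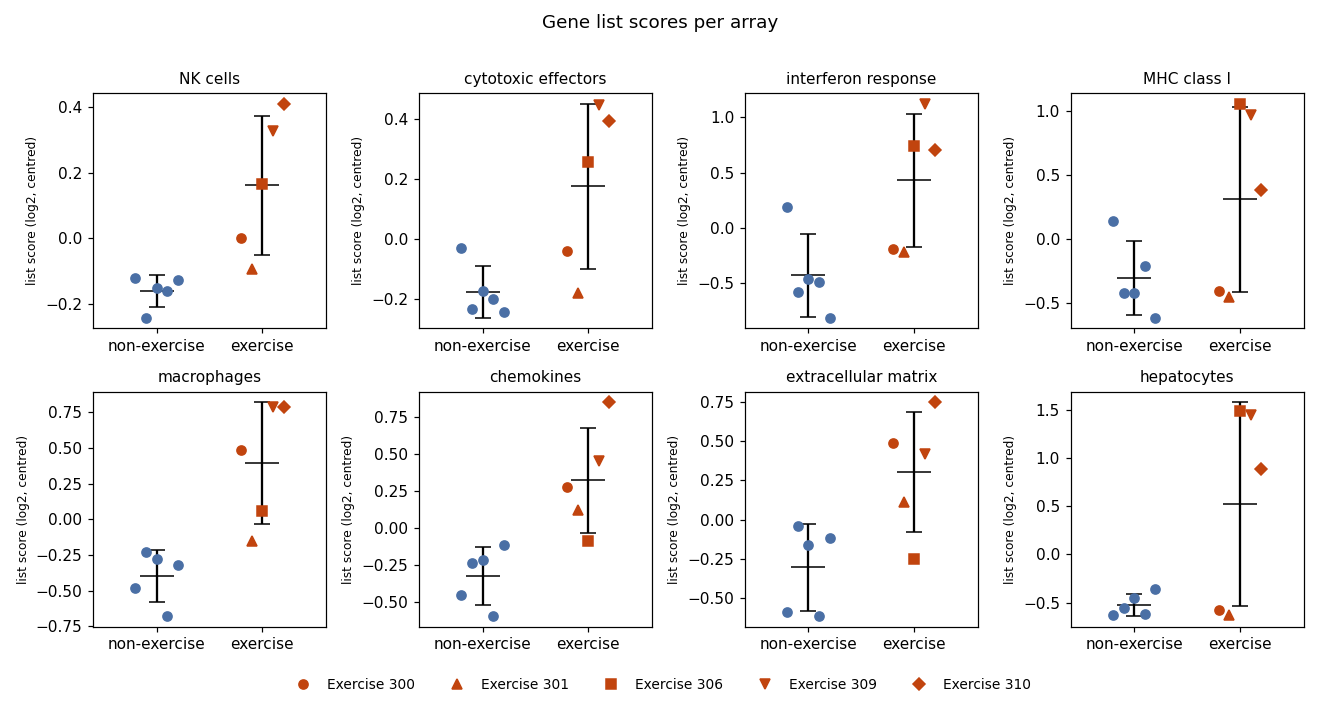
Scores of 8 gene lists per array, as the mean log2 level of the list's genes after centring each gene on its mean over 10 arrays (y axis), for non-exercise (blue) and exercise (orange, one marker shape per array) tumours; bars are the group mean and SD, n = 5. The hepatocyte scores of exercise arrays 306, 309 and 310 lie between 0.89 and 1.5, and the other 7 arrays lie between -0.63 and -0.36.

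Markers of NK cells were higher in the exercise group. The NK cell score was 0.16 ± 0.21 against -0.16 ± 0.05 (SD, n = 5 each). The difference was 0.32 (exact permutation p = 0.00794, two-sided, the smallest that 252 splits of 10 arrays allow). All 5 exercise arrays lay above all non-exercise arrays. Of 22 measured genes of the list, 5 rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 3.78e-07 at the preset correlation and adjusted p = 0.245 with an estimated correlation). Klrk1, which encodes the activating receptor NKG2D, rose by 0.65 ± 0.19 (limma adjusted p = 0.0294), Klrd1 by 0.65 ± 0.15 (limma adjusted p = 0.0102) and Cd244a, a SLAM family receptor, by 0.89 ± 0.14 (limma adjusted p = 0.000845). Ncr1, which encodes NKp46, had a log2 change of 0.39 (limma adjusted p = 0.0845) and Klrb1c, which encodes NK1.1, of 0.25 (limma adjusted p = 0.124). Ncr1 passed without exercise array 301 or 306 (0.49 and 0.46) and Klrb1c without array 306 (0.33). These levels were low, with Klrk1 at 7.27 ± 0.51 in the exercise arrays and 6.62 ± 0.07 in the non-exercise arrays (SD, n = 5 each). The hepatocyte transcripts were in the 3 exercise arrays with the highest NK scores, 0.17 to 0.41. Exercise arrays 300 and 301 lay at 0.00 and -0.09 and the non-exercise arrays between -0.24 and -0.12. Without the 3 arrays the score difference was 0.12 (exact permutation p = 0.0476, the smallest that 21 splits allow) and Klrk1 (0.13), Klrd1 (0.32) and Ptprc (0.62) did not pass, and 1 gene of the list was higher and 1 lower. Klrk1 also lost its call without exercise array 306, 309 or 310, or without any 1 non-exercise array (adjusted p 0.000665 to 0.0714 leaving out 1 array; log2 change from 0.53). The count of 5 NK genes was 2 without exercise array 309 or 310 or non-exercise array 327, 329, 330 or 331. With the adipocyte score as covariate, a setting added after seeing the data, the NK cell score difference was 0.25 and no longer passed (permutation p = 0.0635). Then 2 genes were higher and 0 lower. Ptprc, the gene of the pan-leukocyte marker CD45, rose by 1.16 ± 0.27 (limma adjusted p = 0.00921). With its values subtracted the NK cell score difference was -0.84, since the NK score rose by 0.32 and Ptprc by 1.16. Klrk1 lay at percentile 6.29 of mean level and Ncr1 at 4.69. Klrd1, Cd244a and Klrb1b lay at 25.3, 29.9 and 30.7, and the brighter Ptprc at 61.6. Whether dim levels lower the changes was not tested, so the subtracted score does not measure the share of NK cells among leukocytes. A rise of NK markers that only follows a rise of leukocytes stays open.

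A few genes of the cytotoxic and T cell lists rose, and whole-tumour RNA does not show which cells made them. Of the cytotoxic effector genes 4 of 19 rose and none fell, with 4 adjusted over the list alone (camera adjusted p = 0.000230 at the preset correlation and adjusted p = 0.276 with an estimated correlation). Srgn, the granule proteoglycan serglycin, rose by 1.19 ± 0.19 (limma adjusted p = 0.00109) and Gzmb, granzyme B, by 0.83 ± 0.26 (limma adjusted p = 0.0399), while Prf1, perforin, had a change of 0.37 (limma adjusted p = 0.13) and Ifng, interferon gamma, of 0.23 (limma adjusted p = 0.296). Of the T cell genes 2 of 21 rose and none fell, with 1 adjusted over the list alone (camera adjusted p = 0.000230 at the preset correlation and adjusted p = 0.291 with an estimated correlation). Il7r, the interleukin-7 receptor, rose by 1.33 ± 0.23 (limma adjusted p = 0.00153). Cd8a had a change of 0.30 (limma adjusted p = 0.140), Cd4 of 0.15 (limma adjusted p = 0.447) and Foxp3, the regulator of regulatory T cells, of 0.13 (limma adjusted p = 0.607). Lat changed by -0.24 and did not pass (limma adjusted p = 0.0902). Of the T cell genes 18 had a positive and 3 a negative change. Prf1 and Cd8a passed without exercise array 301 (0.49 and 0.41). Exercise arrays 306, 309 and 310, with the hepatocyte transcripts, held the 3 highest cytotoxic scores (0.26 to 0.45) and T cell scores (0.24 to 0.35), and without them the mean changes were 0.07 (1 higher and 0 lower, not past the list test), and 0.02 (1 higher and 1 lower, not past the list test). Without them Gzmb (0.09) did not pass. Gzmb also lost its call without exercise array 306, 309 or 310 or non-exercise array 327, 329, 330 or 331, and so did Tnfsf10, which encodes the death ligand TRAIL (0.69), and Nkg7, a granule membrane gene (1.03), the last without non-exercise array 326 too (adjusted p 0.00672 to 0.0930, 0.00262 to 0.0990 and 0.00503 to 0.116 leaving out 1 array). The cytotoxic count of 4 was 1 without exercise array 306, 309 or 310 or non-exercise array 327, 329, 330 or 331 and 9 without exercise array 301. Among T cell genes Thy1 (0.57) lost its call without exercise array 300, 309 or 310 or non-exercise array 326, 329 or 330 (adjusted p 0.00687 to 0.0890 leaving out 1 array). The T cell count of 2 was 1 without exercise array 309 or 310 or non-exercise array 326, 329 or 330 and 7 without exercise array 301. With the adipocyte covariate 1 cytotoxic gene and 1 T cell gene were higher.

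Ligands of NK cell receptors changed in both directions. Of 10 measured, 4 rose, 1 fell and 5 did not pass, with 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0310 at the preset correlation and adjusted p = 0.245 with an estimated correlation). Clec2d led the increases, Icam1, the adhesion molecule bound by LFA-1, rose by 0.54 ± 0.12 (limma adjusted p = 0.00955), and Nectin2, a ligand of CD226, changed by -0.32 ± 0.07 (limma adjusted p = 0.00970). H2-Q10, a class I molecule made by liver, changed by 0.50, and lost its call without exercise array 306, 309 or 310 or non-exercise array 329, 330 or 331 (adjusted p 0.00589 to 0.0681 leaving out 1 array). Without the 3 arrays with hepatocyte transcripts H2-Q10 (0.11), Icam1 (0.24) and Nectin2 (-0.26) did not pass, and the list mean was 0.15 (1 higher and 0 lower, not past the list test). The list was not called without exercise array 310 or non-exercise array 330 or 331 (adjusted p 0.00225 to 0.0713 leaving out 1 array). Its count of 4 higher genes was 2 without exercise array 306, 309 or 310 or non-exercise array 329, 330 or 331. That of 1 lower gene was 2 without non-exercise array 330 or 331. With the adipocyte covariate the list did not pass (mean 0.22, with 2 higher and 2 lower genes). Ulbp1 and H60a were not analysed here.

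Interferon-response genes formed the largest increase by its mean among the 35 lists, 0.86 on the log2 scale. Of 30 measured, 15 rose and none fell, and 26 rose when adjusted over the list alone (camera adjusted p = 7.28e-13 at the preset correlation and adjusted p = 0.276 with an estimated correlation). Cxcl10, a chemokine induced by interferon, rose by 1.47 ± 0.19 (limma adjusted p = 0.000263), Mx1, an antiviral GTPase, by 1.35 ± 0.22 (limma adjusted p = 0.00107) and Oasl1 by 1.26 ± 0.22 (limma adjusted p = 0.00153). Of the class I presentation genes 3 of 14 rose, 3 also adjusted over the list alone (camera adjusted p = 3.79e-05 at the preset correlation and adjusted p = 0.375 with an estimated correlation), among them Nlrc5, the class I transactivator, at 0.73 ± 0.17 (limma adjusted p = 0.0107), whose 19 probe sets ranged from 0.31 to 1.45 with 13 past the threshold. Of the class II genes 4 of 11 rose, 5 adjusted over the list alone (camera adjusted p = 0.000526 at the preset correlation and adjusted p = 0.291 with an estimated correlation), with H2-Aa at 1.54 ± 0.40 (limma adjusted p = 0.0167) and the protease gene Ctss at 1.07 ± 0.25 (limma adjusted p = 0.00968). The interferon scores of the 3 arrays with hepatocyte transcripts lay between 0.70 and 1.12, those of the other exercise arrays at -0.22 and -0.19, and those of the non-exercise arrays between -0.81 and 0.19. Without the 3 arrays the mean changes were 0.23 (3 higher and 0 lower, past the list test) for the interferon list, -0.12 (0 higher and 0 lower, not past the list test) for class I and 0.07 (0 higher and 0 lower, not past the list test) for class II. Then H2-Aa (0.39), Nlrc5 (0.29) and Ctss (0.60) did not pass. The interferon count of 15 was 9 without non-exercise array 327, 23 without exercise array 300 and 26 without exercise array 301. H2-T10 (0.34) and the immunoproteasome gene Psmb9 (1.40), the other 2 class I genes that rose, each lost its call without exercise array 306, 309 or 310 or any 1 non-exercise array (adjusted p 0.0102 to 0.0888 and 0.00940 to 0.116 leaving out 1 array). The class I count of 3 was 1 without exercise array 306, 309 or 310 or any 1 non-exercise array, 7 without exercise array 300 and 10 without exercise array 301. Of the class II genes H2-Ab1 (1.25) lost its call without exercise array 306, 309 or 310 or non-exercise array 327, 329, 330 or 331, and H2-Eb1 (1.25) without exercise array 309 or 310 or non-exercise array 327, 329 or 330 (adjusted p 0.00140 to 0.0887 and 0.000512 to 0.0591 leaving out 1 array). The class II count of 4 was 2 without exercise array 309 or 310 or non-exercise array 327, 329 or 330 and 8 without exercise array 301. The adipocyte covariate left 9 interferon genes higher, 1 class I gene higher, and 2 higher and 1 lower class II genes.

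Macrophage, chemokine and complement genes rose as groups. Of 20 macrophage and monocyte genes 14 rose and none fell, with 16 adjusted over the list alone and a median log2 change of 0.88 (camera adjusted p = 7.11e-11 at the preset correlation and adjusted p = 0.245 with an estimated correlation). Itgam, which encodes CD11b, rose by 1.43 ± 0.23 (limma adjusted p = 0.00114), the scavenger receptor gene Msr1 by 1.17 ± 0.20 (limma adjusted p = 0.00173) and Cd68 by 0.76 ± 0.15 (limma adjusted p = 0.00315). Of the chemokines 11 of 23 rose and none fell, with 12 adjusted over the list alone (camera adjusted p = 3.28e-08 at the preset correlation and adjusted p = 0.245 with an estimated correlation), led by Ccl2 at 1.46, Ccl7 at 1.42 and Ccl3 at 1.28, which attract monocytes. Of the complement and coagulation genes 10 of 17 rose and none fell, with 12 adjusted over the list alone (camera adjusted p = 5.13e-08 at the preset correlation and adjusted p = 0.245 with an estimated correlation), including C3ar1 (1.29) and Cfb (1.30). The exact permutation p of the list score was 0.00794 for each of these 3 lists, and 0.0463 after adjustment over 35 lists. The macrophage scores of the 3 arrays with hepatocyte transcripts lay between 0.06 and 0.79, arrays 300 and 301, without them, lay at 0.49 and -0.15, and the non-exercise arrays between -0.68 and -0.23. Without the 3 arrays the mean changes were 0.56 (8 higher and 0 lower, past the list test), for chemokines 0.52 (7 higher and 0 lower, past the list test), and for complement 0.39 (4 higher and 0 lower, past the list test). With the hepatocyte score as covariate the 3 lists passed at the preset correlation with means of 0.62, 0.58 and 0.45, and with 5, 5 and 4 genes higher. The chemokine count of 11 was 6 without exercise array 309 or 310 or non-exercise array 326 or 330 and 7 without exercise array 300 or non-exercise array 329. Adipocyte markers moved with these lists from array to array. The adipocyte scores of exercise arrays 300, 301, 306, 309 and 310 were 0.45, -0.67, -0.10, 0.34 and 1.0, and those of the non-exercise arrays lay between -0.54 and 0.27. In a family of 4 relations chosen after seeing the data, the adipocyte score over the 10 tumours correlated with the macrophage score at r 0.81 (permutation p = 0.00429, adjusted 0.00902; rho 0.72, permutation p = 0.0236; r 0.81 without the 2 farthest). For chemokines and complement r was 0.75 and 0.80 (permutation p = 0.0122 and 0.00451; rho 0.60 and 0.697, permutation p = 0.0730 and 0.0303; r 0.79 and 0.78 without the 2 farthest). Centred within groups, r was 0.88 for macrophages, 0.75 for chemokines and 0.85 for complement (permutation p = 0.000820, 0.0129 and 0.00217). With the adipocyte score as covariate the lists still passed at the preset correlation. Their means were 0.56, 0.47 and 0.43 against 0.79, 0.64 and 0.62, with 14, 6 and 8 genes higher.

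Dendritic cell, neutrophil, checkpoint and entry lists were also higher. Dendritic cell genes rose for 5 of 16, with 8 adjusted over the list alone (camera adjusted p = 4.03e-06 at the preset correlation and adjusted p = 0.245 with an estimated correlation), among them the costimulator gene Cd86 (0.93) and Ccr7 (0.91). Neutrophil genes rose for 4 of 17, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00800 at the preset correlation and adjusted p = 0.375 with an estimated correlation), with Csf3r at 0.72 and Mmp9 at 0.79. Checkpoint and costimulator genes rose for 8 of 17, with 11 adjusted over the list alone (camera adjusted p = 3.38e-06 at the preset correlation and adjusted p = 0.245 with an estimated correlation), including Btla (0.49) and Cd274, which encodes PD-L1 (0.84). Genes for leukocyte entry rose for 3 of 11, with 5 adjusted over the list alone (camera adjusted p = 0.00794 at the preset correlation and adjusted p = 0.245 with an estimated correlation), including Selplg, the selectin ligand gene (1.01). No member of these lists fell over all genes tested, but 1 neutrophil gene passed as lower without exercise array 310 or non-exercise array 326 or 330. Hepatocyte transcripts were in 3 of the 5 exercise arrays here too, and without those arrays the mean changes were 0.19 (2 higher and 0 lower, past the list test), for neutrophils 0.27 (5 higher and 0 lower, past the list test), for checkpoints 0.10 (0 higher and 0 lower, not past the list test), and for entry molecules 0.17 (1 higher and 0 lower, not past the list test), while Ccr7 (0.43), Btla (0.24), Cd274 (0.21) and Selplg (0.39) did not pass. The checkpoint list passed at the preset correlation with the hepatocyte score as covariate (mean 0.15), but with 0 genes higher and 0 lower. The dendritic cell list also had 0 genes higher and 0 lower with that covariate. Counts of higher genes moved when 1 array was left out. For dendritic cells the count of 5 was 3 without exercise array 309 or non-exercise array 327 or 330 and 8 without exercise array 301, and for neutrophils the count of 4 was 2 without non-exercise array 330. For entry molecules the count of 3 was 6 without exercise array 301. The checkpoint count of 8 was 2 without non-exercise array 330, 3 without exercise array 309 or non-exercise array 329 or 331, 4 without exercise array 310 or non-exercise array 326 and 5 without exercise array 306 or non-exercise array 327. With the adipocyte covariate 1 dendritic cell gene and 2 checkpoint genes were higher, and 1 neutrophil gene was called lower. B cell genes (2 of 15 higher and none lower; 2 higher and 1 lower adjusted over the list alone) and mast cell genes (1 higher and 1 lower of 12; 2 and 1 adjusted over the list alone) did not pass as lists, with camera adjusted p = 0.296 and 0.410. The B cell count of 2 was 0 without exercise array 309 or non-exercise array 326 or 329 and 1 without exercise array 300 or 310, and 1 B cell gene passed as lower without exercise array 300 or non-exercise array 331. The mast cell count of 1 higher gene was 0 without exercise array 309 or non-exercise array 326, 327, 330 or 331 and 2 without exercise array 300 or 301.

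Several cytokine and IL-6 pathway genes rose, and Tgfb1 fell. Of 31 cytokine genes 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00874 at the preset correlation and adjusted p = 0.245 with an estimated correlation). Csf1, the macrophage growth factor, rose by 0.85 ± 0.10 (limma adjusted p = 0.000218) and Il1b by 0.97 ± 0.21 (limma adjusted p = 0.00571), while Tgfb1 changed by -0.52 ± 0.08 (limma adjusted p = 0.000973). Of the IL-6 and STAT3 response genes 7 of 18 rose and none fell, with 9 adjusted over the list alone (camera adjusted p = 1.41e-07 at the preset correlation and adjusted p = 0.245 with an estimated correlation), with Il4ra at 1.14, Osmr, the oncostatin M receptor, at 0.75 and Stat3 at 0.35. Il6 itself changed by 0.37 ± 0.12 (limma adjusted p = 0.0476) at a low level (6.41 ± 0.28 in the exercise arrays and 6.04 ± 0.12 in the non-exercise arrays (SD, n = 5 each)), and its receptor Il6ra by 0.53 ± 0.16 (limma adjusted p = 0.0408). Il6 lost its call without exercise array 300, 301, 306 or 310 or non-exercise array 326, 327, 330 or 331, and Il6ra without exercise array 300, 309 or 310 or non-exercise array 326, 329, 330 or 331 (adjusted p 0.0115 to 0.103 and 0.00330 to 0.103 leaving out 1 array). Il15, an NK cell growth factor, had a change of 0.16 (limma adjusted p = 0.612). Of the adrenergic and immediate early genes, 4 of 17 rose, 4 also adjusted over the list alone (camera adjusted p = 0.0437 at the preset correlation and adjusted p = 0.291 with an estimated correlation), including the phosphatase gene Dusp1 (0.54) and Junb (0.52). That list was not called without exercise array 301, 309 or 310 or non-exercise array 330 or 331 (adjusted p 0.0208 to 0.116 leaving out 1 array). Without the 3 exercise arrays with hepatocyte transcripts Il6ra (0.21) did not pass, and the mean changes were 0.19 (5 higher and 2 lower, past the list test), for the IL-6 list 0.26 (4 higher and 0 lower, past the list test), and for the immediate early list 0.11 (3 higher and 0 lower, not past the list test). The immediate early list did not pass with the adipocyte covariate (0.10). The cytokine genes that fell were 2 without exercise array 309.

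**Figure D2:**
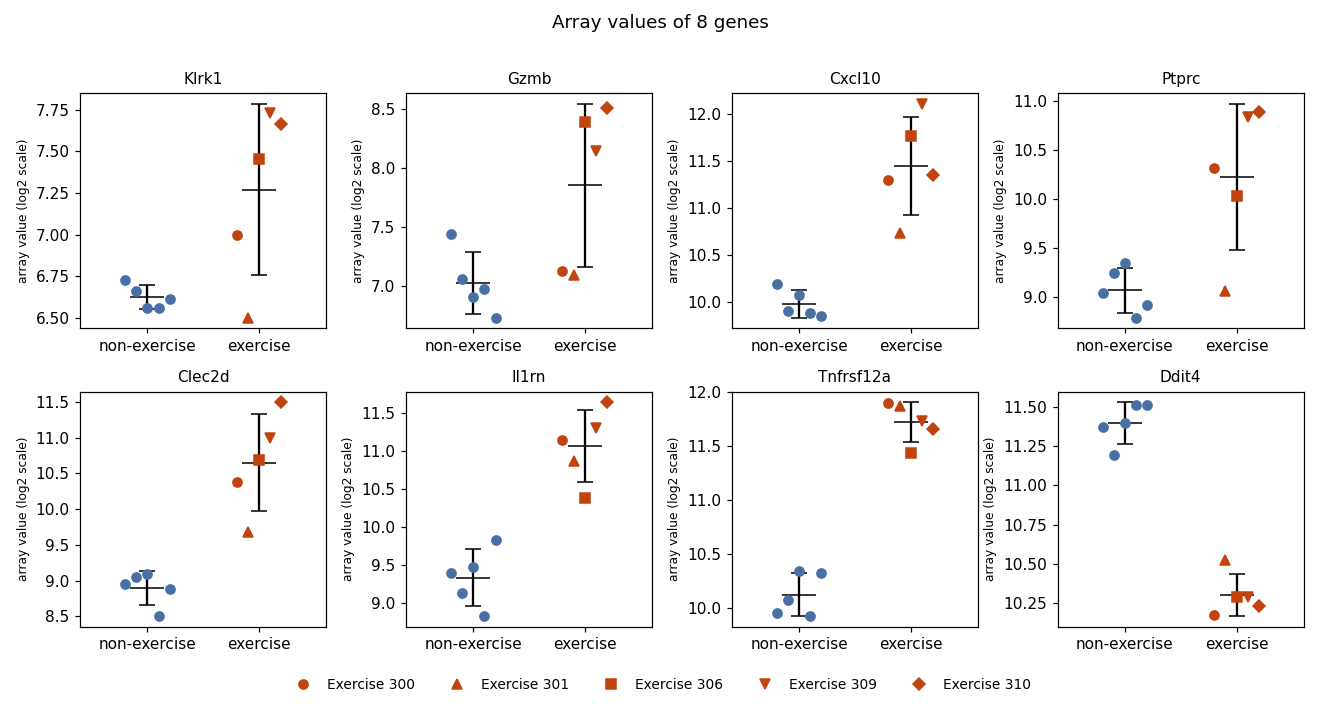
Array values on the log2 scale after quantile normalization (y axis) of 8 genes in non-exercise (blue) and exercise (orange, one marker shape per array) tumours; bars are the group mean and SD, n = 5. For Tnfrsf12a, Il1rn, Clec2d and Cxcl10 all 5 exercise arrays lie above all non-exercise arrays, and for Ddit4 all 5 lie below; for Klrk1, Gzmb and Ptprc the groups overlap.

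Matrix genes rose in the exercise group. Of 29 fibroblast and extracellular matrix genes 17 rose, 1 fell and 11 did not pass, with 24 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.86e-12 at the preset correlation and adjusted p = 0.276 with an estimated correlation). Col1a1 and Col1a2, which encode type I collagen, changed by 0.99 and 1.04, fibronectin, Fn1, by 0.61 and the collagenase gene Mmp13 by 0.85 ± 0.12 (limma adjusted p = 0.000519). The matrix score of exercise array 306 was -0.25, within the range of the non-exercise arrays (-0.62 to -0.04), although it carried hepatocyte transcripts, and without the 3 arrays that carried them the mean change was 0.61 (17 higher and 0 lower, past the list test). With the hepatocyte score as covariate it was 0.65 (9 higher and 0 lower, past the list test). The matrix count of 17 higher genes was 7 without non-exercise array 326 or 330, 9 without exercise array 310 and 10 without exercise array 300 or 309. The 1 lower gene lost its call without exercise array 300, 301, 309 or 310 or non-exercise array 326, 327 or 330. The adipocyte and matrix scores correlated at r 0.77 over the 10 tumours (permutation p = 0.00992, adjusted 0.0122; rho 0.65, permutation p = 0.0502; r 0.86 without the 2 farthest) and at 0.74 centred within groups (permutation p = 0.0128). With the adipocyte covariate 9 matrix genes were higher and the mean was 0.41, past the list test, while the endothelial mean was -0.02 and did not pass. The mean log2 change of the endothelial list was 0.11, and 0.0710 without exercise array 309, 0.0621 without 310 and 0.170 without 301. Endothelial genes were called as a list with 1 higher and 2 lower of 26, the same counts adjusted over the list alone (camera adjusted p = 0.0213 at the preset correlation and adjusted p = 0.588 with an estimated correlation). Vwf rose by 0.55 ± 0.09 (limma adjusted p = 0.000994), while Angpt2 changed by -0.35 and Cldn5, a tight junction gene, by -0.50. The mean of the endothelial list was 0.04 (1 higher and 2 lower, not past the list test) without the 3 arrays with hepatocyte transcripts, where Angpt2 (-0.22) did not pass. Its call was lost without exercise array 309 or 310 or non-exercise array 330 (adjusted p 0.00101 to 0.168 leaving out 1 array). Cldn5 lost its call without exercise array 300 or non-exercise array 327, 329 or 330 (adjusted p 0.0184 to 0.0806 leaving out 1 array). The endothelial count of 1 higher gene was 3 without exercise array 306 and 6 without exercise array 301. That of 2 lower genes was 1 without exercise array 300 or non-exercise array 327, 329 or 330.

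Stress-response and erythroid genes were lower. Of 18 genes of the unfolded protein and integrated stress response, 6 fell and none rose, with 9 lower adjusted over the list alone (camera adjusted p = 0.000375 at the preset correlation and adjusted p = 0.375 with an estimated correlation). Chac1 changed by -0.96 ± 0.17 (limma adjusted p = 0.00230), Sesn2 by -0.87 ± 0.12 (limma adjusted p = 0.000306) and Sdf2l1, an endoplasmic reticulum chaperone partner, by -0.44 ± 0.05 (limma adjusted p = 0.000202). Of 6 erythroid genes 3 fell, with 4 adjusted over the list alone (camera adjusted p = 0.0421 at the preset correlation and adjusted p = 0.245 with an estimated correlation), including Tfrc, the transferrin receptor, at -0.37 ± 0.07 (limma adjusted p = 0.00407). The 3 arrays with hepatocyte transcripts had erythroid scores between -0.38 and -0.34, below all others, and without them the mean changes were -0.21 (0 higher and 1 lower, not past the list test), and -0.20 (0 higher and 3 lower, not past the list test) for the stress list, which passed as lower with the hepatocyte score as covariate (-0.24). The count of 6 stress genes was 3 without exercise array 300 or 309 or non-exercise array 327, 329 or 331 and 10 without exercise array 301. Epb42 (-0.29), a membrane protein gene of red cells, lost its call without exercise array 301, 309 or 310 or non-exercise array 326, 327, 329 or 330, and Slc4a1 (-0.53), which encodes the anion exchanger band 3, without exercise array 300, 306, 309 or 310 or non-exercise array 326, 327, 329 or 330 (adjusted p 0.0219 to 0.103 and 0.00330 to 0.120 leaving out 1 array). With the adipocyte covariate 3 stress genes and 1 erythroid gene were lower, and the erythroid list did not pass (-0.37). The erythroid count of 3 was 1 without exercise array 309 or 310 or non-exercise array 326, 327, 329 or 330. Alas2, an enzyme of heme synthesis in red cells, had a change of -1.39 (limma adjusted p = 0.0615). It passed among the settings that leave out 1 array only without exercise array 301 (-1.94 and adjusted p 0.000165 to 0.153 leaving out 1 array). It also passed after median centring and without genes below the median level. Alas2 was at -0.36 without the 3 arrays and did not pass. The erythroid call was lost without exercise array 309 or 310 or non-exercise array 329 or 330 (adjusted p 0.0105 to 0.0735 leaving out 1 array).

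Melanocytic genes did not pass as a list. Of 20 melanocytic genes 1 rose, 2 fell and 17 did not pass, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.628). S100b changed by -0.44 ± 0.07 (limma adjusted p = 0.00101) and Rab27a, a melanosome transport gene, by -0.28 ± 0.07 (limma adjusted p = 0.0102), while Tyr, tyrosinase, had a change of -0.17 (limma adjusted p = 0.0598), and passed without exercise array 310 (-0.22). Cell cycle genes rose for 2 of 31, none adjusted over the list alone, and the proliferation marker Mki67 had a change of -0.02 (limma adjusted p = 0.871). The cell cycle list passed without exercise array 310 (adjusted p 0.0136 to 0.508 leaving out 1 array; mean log2 change 0.06; adjusted p = 0.127 with all arrays). Hypoxia genes fell for 2 of 26, fatty acid oxidation genes rose for 2 and fell for 4 of 20, oxidative phosphorylation genes rose for 1 and fell for 4 of 26, and each of these counts was the same adjusted over the list alone. Clock genes fell for 4 of 16, also adjusted over the list alone (camera adjusted p = 0.0973). The clock list passed without exercise array 306 and the oxidative phosphorylation list without non-exercise array 331 (adjusted p 0.0356 to 0.239 and 0.0333 to 0.241 leaving out 1 array; mean log2 changes -0.16 and -0.11). Without the 3 exercise arrays with hepatocyte transcripts the clock list passed as lower (mean log2 change -0.21 against -0.13) and the cell cycle list as higher (0.08 against 0.02). These lists also passed with the hepatocyte score as covariate (-0.20 and 0.06). All these calls were made at the preset correlation. With an estimated correlation over all arrays the camera adjusted p was 0.375 for the clock, 0.723 for the cell cycle and 0.600 for the oxidative phosphorylation list. Melanocytic genes fell for 4 of 20 without the 3 arrays, with a list mean of -0.13 (0 higher and 4 lower, not past the list test) against -0.06 with all arrays. In the same setting the hypoxia, fatty acid oxidation and oxidative phosphorylation means were -0.07 (1 higher and 3 lower, not past the list test), -0.06 (1 higher and 5 lower, not past the list test) and -0.10 (1 higher and 3 lower, not past the list test). Housekeeping genes rose for 1 and fell for 2 of 12 (2 and 3 adjusted over the list alone), and nerve genes rose for 2 and fell for 1 of 10, also adjusted over the list alone. The hypoxia, fatty acid oxidation, oxidative phosphorylation, housekeeping and nerve lists did not pass, with camera adjusted p = 0.997, 0.367, 0.105, 0.524 and 0.535. Several of these counts moved when 1 array was left out. The melanocytic gene that rose, Mlph (0.15), lost its call without exercise array 300, 301, 306 or 310 or non-exercise array 326, 327, 329 or 330. The count of 2 higher cell cycle genes was 0 without exercise array 300, 306 or 309 or non-exercise array 326, 327 or 329, 1 without exercise array 301 and 6 without exercise array 310. Without exercise array 300 the called cell cycle genes were 0 higher and 2 lower. No hypoxia gene was called higher with all arrays, and the count was 1 without exercise array 306 or non-exercise array 331 and 2 without exercise array 300. That of 4 lower clock genes was 2 without exercise array 300 or non-exercise array 327 or 329. The count of 2 higher fatty acid oxidation genes was 1 without exercise array 300, 309 or 310 or non-exercise array 326, 329, 330 or 331. That of 4 lower oxidative phosphorylation genes was 1 without non-exercise array 326 or 327 and 2 without exercise array 300, 301 or 310 or non-exercise array 330. For housekeeping genes the count of 1 higher gene was 2 without exercise array 310 and that of 2 lower genes 1 without non-exercise array 330. For nerve genes the count of 2 higher genes was 1 without exercise array 300, 301, 306 or 310 or non-exercise array 326, 327, 329 or 330. That of 1 lower gene was 0 without exercise array 300, 309 or 310 or non-exercise array 326, 330 or 331.

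Among other tissues, adipocyte and skeletal muscle lists were called higher with few members past the test. Of 19 adipocyte genes 1 rose, Retn, and none adjusted over the list alone (camera adjusted p = 0.0105 at the preset correlation and adjusted p = 0.588 with an estimated correlation). Of 22 muscle genes none rose and 1 fell, Eno3, at -0.47 ± 0.12 (limma adjusted p = 0.0162), while the median of the list was 0.30 (camera adjusted p = 0.0280 at the preset correlation and adjusted p = 0.633 with an estimated correlation). The adipocyte call was lost without exercise array 310 or non-exercise array 330, and the muscle call without exercise array 300, 306 or 309 or non-exercise array 330 (adjusted p 1.21e-05 to 0.256 and 0.000286 to 0.336 leaving out 1 array). The adipocyte mean of 0.41 was 0.209 without exercise array 310 and 0.627 without 301. The count of 1 higher adipocyte gene was 0 without exercise array 300, 309 or 310 or non-exercise array 326, 327, 330 or 331, 2 without exercise array 306 and 5 without exercise array 301. The muscle mean of 0.30 was 0.134 without array 306, 0.0493 without 309, 0.542 without 301 and 0.568 without 310. Without the 3 arrays with hepatocyte transcripts the means were 0.09 (0 higher and 1 lower, not past the list test), and -0.02 (0 higher and 1 lower, not past the list test). Keratinocyte genes (0 of 18 past the limma test, and 0 adjusted over the list alone) and lymph node stroma genes (0 of 8 on each count) did not pass as lists, with camera adjusted p = 0.631 and 0.127. Leaving out 1 array, 1 muscle gene passed as higher without exercise array 301. The count of higher stroma genes was 1 without exercise array 306 or 310 or non-exercise array 327 and 2 without exercise array 301, and 1 keratinocyte gene passed as higher without non-exercise array 331 and as lower without exercise array 306 or non-exercise array 326. The mean and median of the keratinocyte list differed in sign (-0.02 and 0.00650), and the mean ran from -0.0389 to 0.00924 leaving out 1 array.

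Of 35 lists tested, 21 were higher and 2 lower at the preset correlation of 0.01, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the lowest adjusted p = 0.245 with an estimated correlation. The exact permutation of list scores, adjusted over the lists, called 6 higher and 0 lower, and 19 had an unadjusted p under 0.05. Of the called lists, the class I, class II, T cell and neutrophil scores had an exact permutation p of 0.119, 0.0635, 0.0556 and 0.0952. The endothelial, adipocyte and muscle scores had an exact permutation p of 0.294, 0.230 and 0.516. None of these lists passed by permutation at 0.05, even unadjusted.

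The NK cell score was correlated with 8 other list scores over the 10 tumours. Exercise arrays 306, 309 and 310, with hepatocyte transcripts, held the 3 highest NK, T cell, cytotoxic, interferon and class I scores. Pearson's r with the T cell score was 0.96 (permutation p = 0.000150, adjusted over 8 relations 0.00120), Spearman's rho was 0.88 (permutation p = 0.00157), and r was 0.91 without the 2 arrays farthest from the median. With the interferon score r was 0.89 (permutation p = 0.00173, adjusted 0.00461), rho 0.85 (permutation p = 0.00252) and r 0.83 without the 2 farthest. Over the 7 arrays without hepatocyte transcripts, a comparison added after seeing the data, none of the 8 relations passed after adjustment, and 1 had an unadjusted exact permutation p under 0.05. There r was 0.67 for T cells (exact permutation p = 0.0875; rho 0.64, exact permutation p = 0.139), 0.67 for cytotoxic effectors (exact permutation p = 0.0980; rho 0.57, exact permutation p = 0.20), 0.43 for interferon (exact permutation p = 0.316; rho 0.68, exact permutation p = 0.110) and -0.0221 for class I (exact permutation p = 0.961; rho 0.0357, exact permutation p = 0.963). Without the 2 farthest of the 7 arrays these r were 0.29, 0.44, 0.93 and 0.07. The calls over 10 tumours were lost without those 3 arrays, where fewer arrays also limit the test. After centring within groups over the 10 arrays, r was 0.95 and 0.77 for the T cell and interferon lists (permutation p = 0.000110 and 0.00930). For T cells r was 0.96 within the exercise and 0.81 within the non-exercise arrays. For interferon these r were 0.88 and 0.33, so the centred relation was weaker in the non-exercise arrays. The relation with lymph node stroma (r 0.82, permutation p = 0.00599; rho 0.72, permutation p = 0.0231) did not hold without the 2 farthest of the 10 arrays, where r was 0.28, and so rested on them. Over the 7 arrays it was 0.68 (exact permutation p = 0.0851, adjusted 0.196; rho 0.61, exact permutation p = 0.167), and 0.83 without the 2 farthest of the 7. With the melanocytic score the sign depended on the arrays used. Within the groups r was 0.91 in the exercise and -0.42 in the non-exercise arrays. NK scores spread more in the exercise arrays (SD 0.21 against 0.05). The positive centred r below thus rests on the exercise arrays and does not hold in both groups. Over all 10 r was 0.03 (permutation p = 0.940; rho -0.10, permutation p = 0.785). It was 0.67 after centring within groups (permutation p = 0.0309, adjusted 0.0497) and -0.79 over the 7 arrays (exact permutation p = 0.0129, adjusted 0.103; rho -0.61, exact permutation p = 0.167; r -0.42 without the 2 farthest). With cytotoxic effectors and class I presentation r over 10 tumours was 0.96 and 0.77 (adjusted permutation p 0.00140 and 0.0210; rho 0.84 and 0.62, adjusted permutation p 0.00955 and 0.0962; r without the 2 farthest 0.91 and 0.70). With the cell cycle and hypoxia scores r was -0.32 and 0.11 (permutation p = 0.373 and 0.788; rho -0.21 and 0.15, permutation p = 0.564 and 0.681). Centred within groups the cell cycle r was -0.65 (permutation p = 0.0431, adjusted 0.0575). The correlation of NK cell score with MHC class I antigen presentation no longer passed without exercise array 309 (r 0.69), and the correlation of NK cell score with lymph node stroma no longer passed without array 309 or 310 (r 0.79 and 0.66).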

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

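The tests of liver RNA, adipose tissue, melanoma share, array scaling, RNA kit or batch and Xist were chosen after the results they bear on were seen; only the counts over other splits of the arrays were not.

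Of 320 groups of 5 arrays tested over list scores and named genes, 16 had 1 array far from the rest, and chance alone gives about 1 in 20, or 16. Exercise array 301 stood apart in Alas2 (11.78), Slc4a1 (7.82), Klrd1 (7.61) and Mmp13 (9.04), array 300 in S100b (10.61), and non-exercise array 326 in Oas2 (9.38) and Oasl1 (9.41). Non-exercise array 330 stood apart in Cd8a (7.81) and Ctss (9.54), and array 331 in H2-T10 (8.45), Mlph (12.17) and Rab27a (12.62). Among scores, array 309 was apart for housekeeping genes (-0.0190), 310 for nerve genes (-0.0410), 326 for checkpoints (-0.0960) and 331 for melanocytic genes (-0.0560). Outside the tested genes, 677 probe sets with no gene in the platform table and 186 with several genes also passed the limma threshold.

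Liver RNA in exercise arrays 306, 309 and 310 is a candidate source of part of the immune increase. Without those arrays the mean score of the macrophage, chemokine and matrix lists differed by 0.56, beside 0.68 with all arrays. The exact permutation p without them was 0.0476, the smallest 21 splits allow, and the difference was 2.65 times the SD of the non-exercise arrays. Both remaining exercise arrays lay above all 5 non-exercise arrays, so this increase was not confined to the arrays with hepatocyte transcripts. The lists were put into 2 sets after their scores were seen, and only 2 exercise arrays remained. This is therefore no independent test of liver RNA as the source. The mean score of the interferon, class I, cytotoxic and T cell lists differed by 0.0484 without the 3 arrays (exact permutation p = 0.810). With all arrays it differed by 0.53 (exact permutation p = 0.0635). For these lists liver tissue and a response to exercise in the same 3 tumours cannot be told apart, because the arrays with hepatocyte transcripts are all exercise arrays. With the adipocyte score as covariate the macrophage, chemokine and matrix difference was 0.48 (permutation p = 0.0159), 3.04 times the residual SD. The covariate stayed with its array while group labels moved, so this p is approximate for the adjusted difference. These values argue against fat, as far as this score measures it, as the whole source, and adipose tissue stays open as part. If a lower share of melanoma cells raised all other cells alike, macrophage and endothelial markers would rise by the same amount. The macrophage score rose by 0.68 more than the endothelial score (exact permutation p = 0.00794), which argues against that form only. The matrix mean rose by 0.61 beside 0.79 for macrophages, and the melanocytic mean was -0.06 (camera adjusted p = 0.628), so a changed share stays open as part. Metastasis to liver, or the way liver or fat tissue came into a sample, was not tested, and the labels name no organ.

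Many genes shifted slightly in 1 direction in all 5 exercise arrays. Of the called genes 81.5% passed in the same direction under both other scalings, so most calls do not depend on which of these scalings was used. All of them start from 1 deposited table whose array medians differed by only 0.126, so differences made before that table were not tested. The deposited maxima lay between 14.43 and 14.55 in the exercise arrays and between 14.32 and 14.36 in the non-exercise arrays. Probe sets with no gene passed 0.578 times as often as brightness-matched probe sets with 1 gene, which decides neither way on an RNA kit or processing batch. Such a batch and the group cannot be told apart, since the labels do not assign kits to tumours, and an effect of exercise was not tested against it.

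For the gene count, only 1 of 100 drawn splits of the arrays, the real one, gave 3384 or more genes, and the highest of the others gave 795. The real split was always among the 100, so 1 of 100 is the smallest share possible. This argues against chance for the gene count without excluding it. For lists chance cannot be excluded, since 5 of 100 splits gave as many as 23 called lists and the highest other split gave 23 (median 13).

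Xist, the RNA of the inactive X chromosome, lay between 9.50 and 11.72 in 9 arrays and at 7.20 in exercise array 301, although all samples are labelled male. Over the 9 arrays Xist and Ptprc, centred within group, correlated at 0.85 (permutation p = 0.00251; rho 0.82, permutation p = 0.0111; r 0.66 without the 2 farthest), which is consistent with Xist coming from cells of the host. The mean of 3 Y-linked genes in array 301 was 0.0772 above the other arrays and lay at 7.81, within their range of 7.45 to 7.99. A host of the other sex for array 301 cannot be told apart from other causes, since Eif2s3y and Uty are dim (7.32 and 6.70 in that array) and the brighter Kdm5d, at 9.41, lay within the range of the others (8.74 to 9.44).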

How the results depend on the processing

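The settings that leave out 3 arrays or use a hepatocyte or adipocyte covariate were chosen after seeing the data. Counts of genes stayed within 1.5 times the reported ones for the other scalings, filters, the mean of probe sets, no trend, robust variances, array weights, the fixed covariates and an adjusted p of 0.10, and leaving out 1 array gave 857 to 1528 higher and 1435 to 2333 lower genes. For genes higher in exercise an ordinary test per gene gave 723. The exact Wilcoxon test gave 0 genes higher in exercise and 0 genes lower in exercise, beside 5822 genes at an unadjusted limma p under 0.05. Its smallest p of 0.00794 needs full separation of the groups, seen for 746 genes above and 1660 below. These were too few to pass after adjustment over 19938 genes. A threshold of 0.25 gave 2667 and 4276. Without the 3 arrays 746 genes were higher, with 11 lists higher and 1 lower, and with the hepatocyte covariate 556 higher, 1353 lower and 12 lists higher; fewer samples and an added term reduce power, and no other cause was tested.

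Lists higher numbered 10 without genes below the median level, 0 with an estimated correlation, 12 with fry and 6 by exact permutation. Lists lower numbered 1 without the dimmest 25% of genes, without those below the median level and with the melanocytic covariate, 0 with an estimated correlation and by exact permutation, and 1 to 3 leaving out 1 array. The reported class I and muscle lists reversed without the 3 arrays (-0.12 and -0.0197) and with the hepatocyte covariate (-0.0591 and -0.17). The adipocyte covariate gave 1 list lower, turned the endothelial mean to -0.0176 and left an NK cell score difference of 0.25 that did not pass. The NK cell score difference reversed only with the brighter Ptprc subtracted (-0.84). Whether changes of the dimmer NK probe sets are on the same scale was not tested. The correlation of NK cell score with melanocytic lineage was -0.16 in the deposited table, -0.23 after median centring and -0.0818 without dim genes, and the correlation of NK cell score with hypoxia and glycolysis was -0.15 after centring. Leaving out 1 array gave -0.32 to 0.17 for melanocytic genes, -0.0904 to 0.236 for hypoxia, -0.43 to 0.17 for the cell cycle, 0.69 to 0.85 for class I and 0.66 to 0.91 for lymph node stroma. With the 3 arrays left out, r was 0.67 for T cells, 0.67 for cytotoxic, 0.43 for interferon, -0.0221 for class I (reversed), -0.79 for melanocytic, 0.43 for cell cycle, -0.15 for hypoxia and 0.68 for stroma genes, none past the adjusted test over 7 arrays. The cause was not tested. Pseudocounts were not run on a table already on a log scale, and the stroma list was too small without dim genes.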

Other observations

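The lists in this part were written after the values were seen, so their counts are no independent evidence of direction. Of 15 measured cholesterol synthesis genes 13 fell and none rose in exercise, 14 adjusted over the list alone, with Mvd at -0.80 ± 0.12 (limma adjusted p = 0.000598), Mvk at -0.71 ± 0.08 (limma adjusted p = 0.000157) and Hmgcs1 at -0.41 ± 0.08 (limma adjusted p = 0.00249) (score difference -0.36, exact permutation p = 0.00794; adjusted p = 0.149 with an estimated correlation). Of 27 splicing factor genes 13 rose and none fell, 14 adjusted over the list alone, with Leng8 at 0.63 ± 0.06 (limma adjusted p = 5.58e-05), Ddx17 at 0.52 ± 0.06 (limma adjusted p = 0.000218) and Tra2a at 0.51 ± 0.07 (limma adjusted p = 0.000371) (exact permutation p = 0.00794; adjusted p = 0.105 with an estimated correlation). Of 32 mitochondrial ribosome genes 1 rose and 8 fell, 2 and 9 adjusted over the list alone, with Mrpl14 at -0.47 ± 0.06 (limma adjusted p = 0.000253) (exact permutation p = 0.0317; adjusted p = 0.493 with an estimated correlation).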
